A study of Mus musculus with 21 samples.

How the data were processed

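The series measured polyadenylated RNA of single mouse cells with the droplet-based 10x Chromium Single Cell 3' v3.1 dual index assay, in which each captured transcript carries a unique molecular identifier (UMI) and is read near its 3' end. The 21 libraries comprised 16 from mouse embryonic fibroblasts (MEFs) transduced with lentivirus, 2 from MEFs that were wildtype and not sorted for a reporter, and 3 from splenic dendritic cells (DCs). The transduced libraries formed 8 arms, an arm being a factor set in a reporter line, each collected at day 3 and at day 9. The factor sets were PI8 (Spi1, which encodes PU.1, with Irf8), PIB (PI8 with Batf3), PI4 (Spi1 with Irf4), PIP (PI4 with Prdm1), SI8 (Spib with Irf8) and SII (SI8 with Ikzf2). All sets were delivered to fibroblasts of a Clec9a-Cre tdTomato reporter line, and SI8 and SII also to fibroblasts of an hCD2 reporter line with YFP. Per the labels' protocols, live reporter-positive cells were sorted from the transduced cultures. The splenic populations were sorted by surface proteins as type 1 conventional DCs (cDC1), type 2 conventional DCs (cDC2) and plasmacytoid DCs (pDC).

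The deposited values were whole-number UMI counts per gene and cell in 1 table of 24455 gene symbols and 25991 cells. The authors used Cell Ranger 6.0.1, Seurat and the genome build mm10, per the submitters' processing notes; the version of Seurat and the filters on cells were not given in the sources used here. Every deposited column belonged to a library of the labels, and 0 columns were left unassigned. Deposited cells held 2501 to 99996 UMIs and 791 to 8783 genes. The table gave gene symbols without coordinates, so genes are named by symbol. Genes with near-identical copies (the H2 genes, Lilrb4a and Lilr4b, Pira2, the Ifit genes, Ccl8 with Ccl12, and Gm42418) are uncertain, since the counting could split or drop their reads.

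Cells were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial counts over 13 mitochondrial genes, which removed 0 cells. No doublets were removed in the main results. Scrublet, run per library through scanpy 1.11.5, called 170 cells (0.65%), and these were left out as an alternative. Counts were summed over the kept cells of each library. Library totals ran from 2291128 UMIs (SI8, hCD2 line, day 3) to 89394715 UMIs (SII, Clec9a line, day 3), and median UMIs per cell from 2765 to 82866. The totals in the fits were 39630573 and 47984915 for the MEF libraries. At day 3 they were 31118230 for PI8, 47373112 for PIB, 16767937 for PI4, 76033948 for PIP, 86566455 for SI8 and 72530171 for SII in the hCD2 line. At day 9 they were 6194472 for PI8, 38743525 for PIB, 7882881 for PI4, 84879042 for PIP, 17363435 and 4651950 for SI8 and 29149395 and 60926826 for SII, the Clec9a line given before the hCD2 line. The splenic totals were 13208494 for cDC1, 23357225 for cDC2 and 53142916 for pDC. Levels are given as CPM (UMI counts of a gene scaled by the total of its library) with exact Poisson 95% intervals, and shares of cells with exact Clopper-Pearson 95% intervals. These intervals, and the limit of 3 counts that stands in for a count of 0, cover counting error only.

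The 2 MEF libraries shared 0 cell barcodes, and a chi-square test of their counts over 14132 genes gave 2.46 per degree of freedom, so they were treated as separate libraries. No source said that any libraries came from separate animals or cultures, and the arms hold different factor sets and are not replicates of each other. The p-values therefore measure the spread between these libraries, which may be technical. A check of whether the libraries of an arm carried matching genotype-dependent transcripts covered 8 arms, and in 1 arm the libraries did not match.

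Groups, tests, covariates, gene lists, named genes and most alternatives were fixed before the data were examined. Differences between libraries were tested on the summed counts with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, R 4.3.3), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes come from that test, and all tests were two-sided. Day 9 and day 3 were each compared with MEF in a fit of 18 libraries with 3 groups (15 residual degrees of freedom). Day 9 was compared with day 3 over the 16 transduced libraries with the arm as a block, because the labels pair the days within an arm (7 residual degrees of freedom). The same fit gave the contrasts PIB minus PI8, PIP minus PI4, and PI8 minus SI8 in the Clec9a line. In these contrasts each side had a single library per day, and the pairs are its day 3 and day 9 libraries. Their p-values ask whether the difference held at both days against the arm-by-day spread over all arms. They do not measure the spread between transductions. Irf4 arms (PI4 and PIP) were compared with Irf8 arms (PI8 and PIB) over 8 libraries with day as a covariate. The 8 libraries of SI8 and SII gave the Ikzf2 contrast and the reporter line contrast, each with the other factor and day as covariates (4 residual degrees of freedom). In these contrasts and between Irf4 and Irf8 arms, both days of an arm entered as separate libraries without the arm as a block. No source said whether both days of an arm came from separate transductions, so these p-values may not measure that spread. An interaction of day with Spi1 or Spib was tested over all 16 transduced libraries. Another scaling could move the zero point of these fold changes. The median log2 fold change of all genes was 0.19 at day 9 and 0.14 at day 3 against MEF.

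The 21 gene lists held 293 genes, of which 287 were in the table. They were delivered factors, cDC1, cDC2, pDC, pan-haematopoietic and pan-DC, MHC class II presentation, MHC class I presentation, fibroblast and extracellular matrix, contractile, interferon response, cytokines and chemokines, mature DC, pattern recognition, cell cycle, macrophage and monocyte, neutrophil and mast cell, B cell, T and NK cell, erythroid and platelet, endothelial, epithelial and muscle, and stress. Each was tested with fry of limma 3.58.1, whose p asks whether the members moved on balance in 1 direction, and with camera with an estimated correlation between genes as the alternative. fry does not compare a list with other genes. Adjusted p-values of lists were adjusted over the lists of a comparison. The text names the delivered factors, then the 8 genes with the highest and the 8 with the lowest fold change among called genes with at least 50 CPM on 1 side that moved the same way in every pair of libraries (against MEF, with all transduced libraries on the same side of both MEF libraries), leaving out predicted genes, and up to 4 members of each described list with the smallest adjusted p. Where a side had 0 counts, the fold is given as a lower bound against 3 counts over the group. Where it had 1 to 3 counts, the ratio of the mean CPM of the other side to its pooled CPM (counts over summed totals) is given with its counting interval.

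Comparisons with splenic DCs had 1 library per population and no test. The share of the gap closed was the median over genes of the distance of a library from MEF divided by the distance of the splenic library from MEF, on log2(CPM + 10), over genes at least 4-fold apart with at least 50 CPM in the higher. Its interval came from 200 resamplings of cells. List medians were ranked among 10000 random lists of equal size matched on mean expression in 50 bins. Shares of cells with a UMI were taken after thinning each cell to 5400 UMIs, which left out 2575 shallower cells. Cells were clustered on 2000 variable genes without the delivered factors, 30 principal components and 15 neighbours with leidenalg 0.10.2 at resolution 0.5, without batch correction. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

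The fits were tested on simulated counts with 200 genes changed. Apart from these changes and from depth, the simulated libraries shared a common mean level per gene. They held no differences between arms and no library that lay apart, so the shares recovered may not hold for the real fits. At a 4-fold change, the test recovered 21% of genes for day 9 against MEF (16202 genes), 100% for day 9 against day 3 (15625 genes), 27% for Irf4 against Irf8 arms (14120 genes), 100% for the Ikzf2 contrast (15036 genes) and 42% for the Batf3 contrast (15602 genes). At a 2-fold change the shares were 0%, 42%, 0%, 63% and 1% in the same order. False calls made up 10% of the calls for Irf4 against Irf8 arms, above the nominal 5%, and 0% to 4.4% for the others.

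Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, a stricter filter on cells (at least 1000 genes and at most 10% mitochondrial counts), removal of called doublets, counts thinned to the shallowest library, other sets of libraries or covariates, each library left out in turn, other pseudocounts and fold limits for the gap, other thinning depths and other cluster resolutions. Leaving out the library labelled PI8 day 9, keeping only cells with at least 10000 UMIs, leaving out both SI8 libraries of the hCD2 line, and their combinations were chosen after the data were seen. Comparisons of single transduced libraries with MEF were left out, because each would rest on 1 library.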

Results

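Fibroblasts carrying 6 sets of haematopoietic transcription factors were profiled as single cells at day 3 and day 9 after transduction and set against untransduced fibroblasts and splenic dendritic cells (DCs). The deposited table held 25991 cells from 21 libraries. These were 2 libraries of mouse embryonic fibroblasts (MEFs; 2045 and 1728 cells), 16 transduced libraries (411 to 2081 cells) and 1 library each of cDC1 (814 cells), cDC2 (1881 cells) and pDC (4169 cells). Depth differed widely between libraries, from a total of 2291128 UMIs to 89394715 UMIs. Median UMIs per cell were lowest in the SI8 libraries of the hCD2 line, at 2765 on day 3 and 2786 on day 9, and highest in PI8 at day 3, at 82866.

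The delivered factors were read first, as a check of the labels. Spi1, which encodes PU.1, a regulator of myeloid and B cell genes, had 0 UMIs in both MEF libraries, which allowed at most 0.0931 and 0.0769 CPM. It reached 93.4 CPM in PI8 at day 3 and 215.4 CPM (95% interval 204.0 to 227.2) at day 9, and 9.26 to 49.2 CPM in PIB, PI4 and PIP. Irf8, a factor needed for cDC1 development, lay at 18.7 to 94.5 CPM in the 12 libraries of sets that contain it and at 0.25 to 0.53 CPM in PI4 and PIP. Irf4 reached 10.0 and 7.10 CPM in PI4 and 18.5 and 16.6 CPM in PIP. Prdm1, which encodes the repressor BLIMP1, reached 85.4 and 66.2 CPM in PIP, with 9.08 and 9.00 CPM in MEF. Spib, a relative of Spi1 expressed in pDCs, lay at 6.52 to 32.3 CPM in SI8 and SII. Ikzf2, which encodes the zinc finger protein HELIOS, reached 91.1 and 104.9 CPM in SII at day 3 and 26.9 and 26.8 CPM at day 9, with 10.1 and 9.71 CPM in MEF. Raised counts also appeared in sets without the factor. Ikzf2 stood at 58.3 CPM (52.4 to 64.6) in the library labelled PI8 day 9, above SII at day 9. Prdm1 reached 28.45 and 15.84 CPM in SII at day 3 and 15.1 CPM in PI8 at day 3. Batf3, a factor required for cDC1s, did not stand out in the set that contains it. It stood at 5.0 and 2.32 CPM in the libraries labelled PIB, beside 6.11 CPM in PI8 at day 3, 0 in the library labelled PI8 day 9 and 268.4 CPM in cDC1. The counts cannot tell viral from endogenous transcripts, and a 3' tag outside the delivered coding sequence checks nothing.

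**Figure D1:**
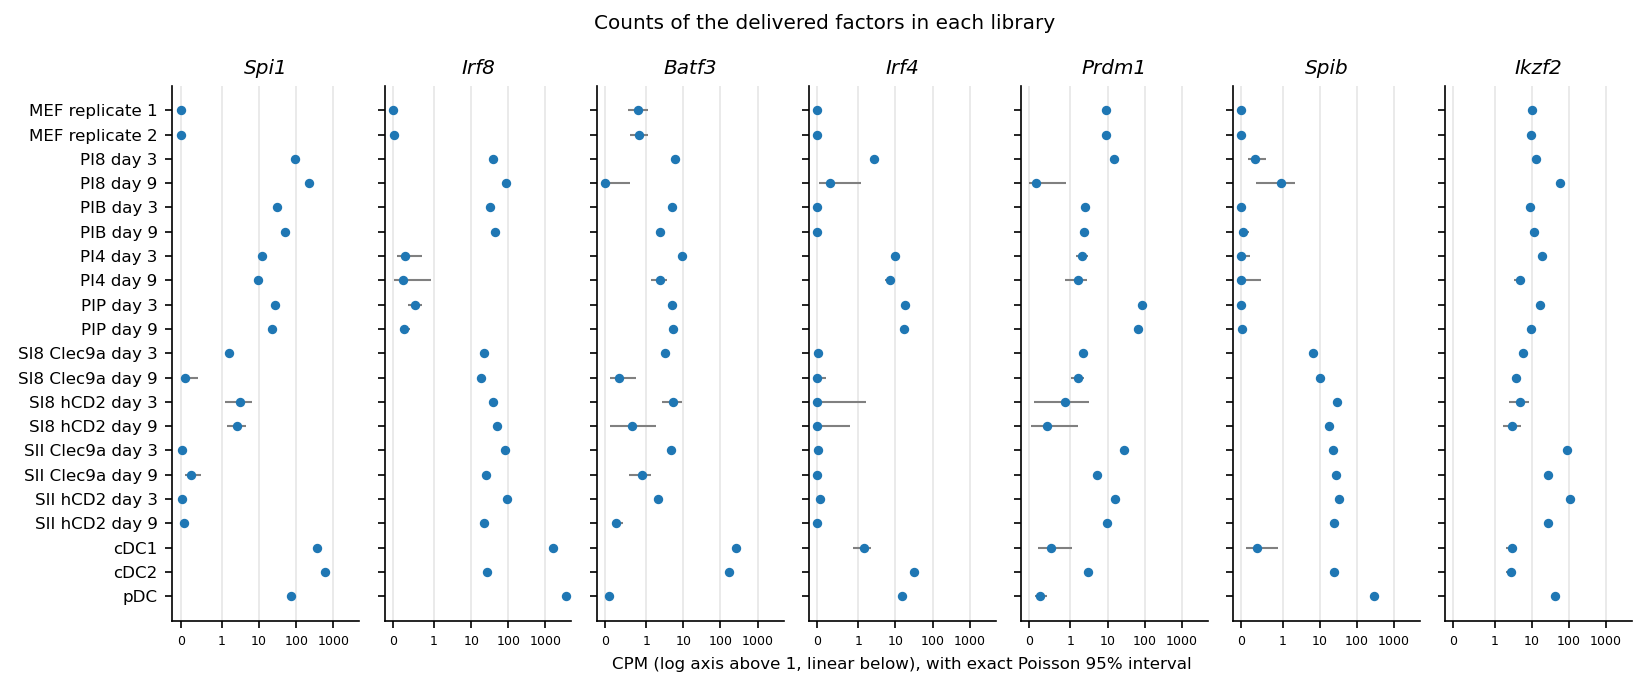
CPM of each delivered factor in the 21 libraries (x axis logarithmic above 1 and linear below; bars are exact Poisson 95% intervals). Spi1 reached 215.4 CPM in the library labelled PI8 day 9 and was at 0 in both MEF libraries, and Batf3 stood at 5.0 and 2.32 CPM in the libraries labelled PIB.

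Day 9 cells were compared with MEF to ask which genes all factor sets moved. Transcripts of haematopoietic cells appeared and part of the structural genes of fibroblasts fell. Cd53, a leukocyte tetraspanin, rose by a log2 fold change of 11.74 ± 1.60 (SE; 203.1 CPM on average against 0.0543, adjusted p = 0.000275). Ctss, a protease that processes antigen for MHC class II, rose by 8.73 ± 1.30 (adjusted p = 0.000584). Both lay above both MEF libraries in 8 of 8 libraries. Genes with 0 counts in MEF were at least 6949-fold higher for the inhibitory receptor Lilrb4a (237.9 CPM, adjusted p = 0.0011) and at least 6409-fold for the scavenger receptor Cd36 (adjusted p = 0.00218). The bound was 4863-fold for Clec12a, a lectin of cDC2s and pDCs (adjusted p = 5.92e-05), each in 8 of 8 libraries. Aif1 was at least 5179-fold, Lilr4b at least 4437-fold, Pld4 at least 2440-fold and Ccr2 at least 1885-fold higher, in 8 of 8 libraries. Cd52, with 1 count in MEF, had a ratio of 25520 (counting interval 4580 to 1008000, adjusted p = 0.024). Falling genes were led by the acute-phase inhibitor Serpina3n (-8.21 ± 0.92, adjusted p = 5.74e-05), the chemokine Cxcl15 (-8.65 ± 1.09, adjusted p = 0.000132) and the imprinted transcript H19 (-7.85 ± 1.25). They also included Fxyd1 (-7.29 ± 0.97), Abi3bp (-7.13 ± 0.83), Chl1 (-6.94 ± 1.40), Cxcl5 (-6.85 ± 1.72) and Sfrp2 (-6.74 ± 1.31), all below both MEF libraries in 8 of 8 libraries.

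By group, 11 of 20 tested fibroblast and matrix genes fell and 0 rose at day 9 (13 adjusted over the list alone; list adjusted p = 0.00399 by fry). The list had an adjusted p = 0.287 with an estimated correlation. Collagens were among them, with Col3a1 at 58.4 CPM against 6085 in MEF (-6.69 ± 1.06, adjusted p = 0.000951) and Col1a1 at 89.8 against 5423 CPM (-5.85 ± 1.02). Col6a1 (-5.74 ± 0.72) and the receptor Pdgfra (-4.60 ± 0.84) fell as well, each gene in 8 of 8 libraries. In the pan-haematopoietic list 5 of 17 genes rose (16 adjusted over the list alone; list adjusted p = 0.00777, and adjusted p = 0.287 with an estimated correlation). They included Ptprc, the CD45 phosphatase (at least 1424-fold, adjusted p = 0.0336), and Laptm5 (10.10 ± 2.57). Of 10 cDC2 genes 3 rose (5 adjusted over the list alone), namely Clec12a, the integrin Itgam (at least 674-fold, adjusted p = 0.00156) and Clec4a2 (at least 250-fold; 7 of 8 libraries). This list alone kept its call under camera (adjusted p = 0.000117 by fry, and adjusted p = 0.0254 with an estimated correlation). Of 14 cDC1 genes 2 rose (2 adjusted over the list alone), namely the repressor Id2 (4.85 ± 1.29; 7 of 8 libraries) and the adhesion molecule Cadm1 (6.57 ± 1.86; 8.26 CPM). The cDC1 list had an adjusted p = 0.0189, and adjusted p = 0.384 with an estimated correlation. MHC class II genes rose in 4 of 12 cases (9 adjusted over the list alone). Cd74, the invariant chain, stood at 677.7 CPM against 17.3 (5.44 ± 1.65, adjusted p = 0.0432). Ctss, H2-Aa and Cd86 were also called, while the list missed the threshold (adjusted p = 0.0546). Cytokines gave 3 called genes of 16, all higher (3 adjusted over the list alone), namely Il1b (at least 8401-fold; 7 of 8 libraries, adjusted p = 0.0488), Ccl3 and Tnf. Members named here without a number of libraries moved the same way in 8 of 8, except Cd86 in 7. Members of the contractile, MHC class I, cell cycle and stress lists were not called, and the contractile, mature DC and B cell lists had positive medians (0.40, 0.44 and 2.93) where the test pointed down.

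At this level 1746 of 16538 genes were called at day 9, 829 higher and 917 lower, and 1458 of them changed at least 2-fold. DESeq2 called 3289 genes and moved the share that was higher from 47.5% to 61.2%. The count fell to 264 without MEF replicate 1 and to 267 without MEF replicate 2, where Cd36, Aif1, Lilr4b, Pld4, Ccr2, Cd52 and Cxcl5 were no longer called (adjusted p of 0.0531 to 0.271). It rose to 3310 without the library labelled PI8 day 9, in which the fibroblast list summed to 32.0 CPM against at least 1843 CPM in every other transduced library, and all 1746 genes were among these. Aif1 and Cd52 also lost their call in counts thinned to the shallowest library (1098 genes) and with day 9 and MEF libraries alone (1058 genes), at adjusted p of 0.0502 to 0.0649. Virus, reporter genotype and sort went with this contrast, and so did RNA quality, since Gm42418, AY036118 and Lars2 took 0.08% of the counts in both MEF libraries and 0.15% to 10.81% in the transduced libraries.

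By day 3 the same comparison with MEF already called 2825 genes, 1439 higher and 1386 lower. Clec12a was at least 4223-fold higher (adjusted p = 4.66e-05) and Il1b, a proinflammatory cytokine, at least 8717-fold (298.5 CPM, adjusted p = 0.0355). Aif1 was at least 6910-fold, Pld4 at least 3777-fold, Lilrb4a at least 3660-fold and Ptprc at least 1810-fold higher (adjusted p = 0.021). All were higher in 8 of 8 libraries. Cd53 rose by 10.81 ± 1.55, Cd74 by 6.21 ± 1.72 (1142 CPM, adjusted p = 0.0204), Cadm1 by 7.94 ± 1.97 (21.1 CPM) and Id2 by 5.19 ± 1.32. Ciita, the master regulator of MHC class II genes, had a ratio of 267 (73.9 to 2205, adjusted p = 0.0363). Lower genes included Cxcl15 (-10.70 ± 1.18), Fxyd1 (-9.93 ± 1.08), the plasma protein Hp (-9.12 ± 1.25), Serpina3n (-8.84 ± 0.93), the matrix protease Mmp3 (-7.04 ± 1.85), Lum (-6.85 ± 1.26) and Col3a1 (-6.76 ± 1.06; 49.7 CPM), in 8 of 8 libraries. Of the lists, fibroblast genes fell in 11 of 20 cases (14 adjusted over the list alone, adjusted p = 0.00617, and adjusted p = 0.299 with an estimated correlation). The cDC2 genes rose in 2 of 10 (4 over the list alone, adjusted p = 0.000244, and adjusted p = 0.0869 with an estimated correlation). MHC class II genes rose in 5 of 12 (10 over the list alone, adjusted p = 0.033, and adjusted p = 0.452 with an estimated correlation). Macrophage genes went both ways, with Cd68 (4.59 ± 1.12) higher and the lipid carrier Apoe (-2.52 ± 0.78) and Spp1 (-3.79 ± 1.11) lower than MEF, and 4 of 18 called in all. The count was 4371 by DESeq2, 1700 in thinned counts, 4451 without the library labelled PI8 day 9, 566 without MEF replicate 1 and 561 without MEF replicate 2, and the share that was higher went from 50.9% to 26.5% and 27.8% in these 2. Il1b, Aif1, Pld4, Ptprc, Cd52 and Mmp3 were not called without either MEF library (adjusted p of 0.0705 to 0.249).

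Day 9 was compared with day 3 within each arm. Over all 8 arms 13 of 16090 genes were called, 6 higher and 7 lower. Clec4e, the receptor MINCLE, rose by 5.60 ± 0.48 (11.8 against 0.218 CPM, adjusted p = 0.00874) and Apoe by 2.72 ± 0.35 (140.6 against 16.6 CPM, adjusted p = 0.0271), each in 8 of 8 arms. Dlk1, a NOTCH ligand of fetal stroma, fell by 2.79 ± 0.34, Samhd1, a nuclease of deoxynucleotides, by 1.29 ± 0.16 and Jpt1 by 0.77 ± 0.10 (adjusted p = 0.0271 for each; 8 of 8 arms). No list passed the threshold (lowest adjusted p = 0.051). Apoe, Dlk1, Samhd1 and Jpt1 kept their direction but not their call when single libraries were left out. DESeq2 called 1203 genes and thinned counts 7, and leaving out the PIB, PI4, SI8 or SII libraries in turn left 3 to 5.

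RNA quality moved with day. The share of Gm42418, AY036118 and Lars2 was higher at day 9 in 7 of 8 arms and the median mitochondrial share lower in 6 of 8, and barcodes under 10000 UMIs went from 0.93% to 46.8% in SI8 and from 0.48% to 21% in SII of the Clec9a line. The count rested on the PI8 libraries. Without the library labelled PI8 day 9, 1272 genes were called (577 higher, 695 lower), the 13 among them, and without PI8 at day 3 there were 1232. Macrophage genes then rose in 6 of 18 cases (9 adjusted over the list alone; list adjusted p = 0.0321, and adjusted p = 0.326 with an estimated correlation). Lysozyme Lyz2 rose by 4.12 ± 0.94 (2662 against 411.8 CPM, adjusted p = 0.0338), as did the scavenger receptor Marco (3.79 ± 0.76) and Apoe (2.83 ± 0.36, adjusted p = 0.00647), in 7 of 7 arms. The highest folds among genes at 50 CPM or more included the neuropeptide Nts (4.21 ± 0.76), serum amyloid Saa3 (3.79 ± 0.96; 6111 against 2389 CPM) and Wfdc17 (3.66 ± 0.58). The lipocalin Lcn2 (3.24 ± 0.62) and the elastase Mmp12 (3.06 ± 0.46) followed, again in 7 of 7 arms. The cDC2 list rose in 3 of 11 cases (5 adjusted over the list alone, adjusted p = 0.0426, and adjusted p = 0.369 with an estimated correlation), with the lectin Cd209a at 95.4 against 15.9 CPM (2.20 ± 0.36, adjusted p = 0.0123). Fibroblast genes rose in 4 of 20 cases (6 adjusted over the list alone), including Dcn (2.67 ± 0.47; 657.9 against 164.4 CPM) and Postn (1.73 ± 0.26). Cell cycle genes fell in 3 of 18 (9 adjusted over the list alone), including Ccnb1 (-1.97 ± 0.37) and Mcm3 (-0.82 ± 0.12). Both lists fell short of the threshold (adjusted p = 0.0777 for each). Of 14 cDC1 genes 2 fell, Cadm1 (-1.63 ± 0.40) and Naaa (-1.58 ± 0.22), and the interferon genes Oasl1 (-2.11 ± 0.33) and Usp18 (-0.81 ± 0.13) fell as well. The pattern recognition list had a median of -0.12 where its test pointed up. With cells of at least 10000 UMIs and without that library 875 genes were called.

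Adding Ikzf2 to Spib and Irf8 was tested in 4 matched pairs of SII and SI8 libraries (2 days in 2 reporter lines). Of 15423 genes 5798 were called, 2897 higher and 2901 lower, and 3570 changed at least 2-fold. These were more calls than in any other factor contrast with all libraries in the fit. The counts do not rank the factors by effect, because the fits differed in libraries, spread and power. In simulated counts this fit recovered 63% of genes changed 2-fold, against 1% for the Batf3 contrast and 0% for Irf4 against Irf8 arms. RNA quality moved with this contrast. The transcripts Gm42418, AY036118 and Lars2 took 8.32% and 10.81% of the counts in SI8 of the hCD2 line and 0.29% and 3.66% in SI8 of the Clec9a line, against 0.15% to 0.59% in SII. The median mitochondrial share was 0.198% to 1.93% in SI8 and 2.87% to 4.14% in SII. Macrophage, chemokine and antigen presentation genes were lower with Ikzf2. Timd4, a receptor for apoptotic cells, fell by 12.79 ± 0.78 on the log2 scale (0.0217 against 118.2 CPM, adjusted p = 7.53e-05) and the protease Ctsk by 8.49 ± 0.41 (adjusted p = 3.54e-05). Ccl8 fell by 9.62 ± 0.83 (28.5 against 11690 CPM, adjusted p = 0.000264) and Slamf7 by 11.40 ± 0.76. Saa3 fell by 9.60 ± 1.58, Lyz2 by 9.10 ± 1.57 (62.2 against 5021 CPM, adjusted p = 0.00416) and Lce1g by 8.72 ± 0.56, all in 4 of 4 pairs. The B cell chemoattractant Cxcl13 had 0 counts in SII and was at least 8129-fold lower (adjusted p = 0.00111). Rising genes were the peptide receptor Qrfpr (7.60 ± 0.51, adjusted p = 0.000115), Ptprc (5.56 ± 1.10; 138.5 against 2.78 CPM, adjusted p = 0.00702) and the tight junction gene Cldn1 (5.43 ± 0.37). They also included Fgl2 (4.91 ± 0.55), Pira2 (4.52 ± 0.72), Dlk1 (4.15 ± 0.58), Auts2 (4.12 ± 0.41) and Btbd3 (4.09 ± 0.64), in 4 of 4 pairs. Ikzf2 itself rose by 3.30 ± 0.28 (62.4 against 4.32 CPM, adjusted p = 0.000257). Irf8 and Spib, present on both sides, differed by 0.33 ± 0.47 (adjusted p = 0.604) and 0.71 ± 0.33 (adjusted p = 0.118).

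The lists described where these genes fell. Of 17 interferon response genes 15 fell and 1 rose (list adjusted p = 0.00105, and adjusted p = 0.206 with an estimated correlation). Among them were Oasl2 (-7.50 ± 0.54), Ifit2 (-6.29 ± 0.38) and Rtp4 (-5.70 ± 0.41). Of 12 MHC class II genes 9 fell and 1 rose (adjusted p = 0.00488, and adjusted p = 0.229 with an estimated correlation). H2-Eb1 stood at 6.10 against 205.5 CPM (-5.21 ± 0.61), and the costimulatory receptor Cd40 fell as well (-4.45 ± 0.47). MHC class I genes fell in 8 of 13 cases (adjusted p = 0.0042, and adjusted p = 0.229 with an estimated correlation). They included the immunoproteasome subunits Psmb9 (-2.51 ± 0.28) and Psmb10 (-2.03 ± 0.18). Cytokine genes fell in 12 of 16 cases (adjusted p = 0.00368, and adjusted p = 0.206 with an estimated correlation). Il1b stood at 9.87 against 776.5 CPM (-6.88 ± 0.58) and Cxcl16 at 24.9 against 963.4 CPM (-5.58 ± 0.23, adjusted p = 2.49e-05). Macrophage genes fell in 12 of 18 cases (adjusted p = 0.00105, and adjusted p = 0.144 with an estimated correlation), with Fcgr1 at least 406.5-fold lower. The direction was opposite in the pan-haematopoietic list, where 9 of 17 genes rose and 2 fell (adjusted p = 0.0279, and adjusted p = 0.375 with an estimated correlation). Risers included the cytoskeletal regulator Coro1a (2.64 ± 0.17, adjusted p = 9.77e-05), the signalling adaptor Vav1 (4.85 ± 0.57) and the integrin Itgb2 (3.86 ± 0.37), while Cd52 fell (-4.32 ± 0.42). Adjusted over the list alone, 16 interferon, 10 MHC class II, 8 MHC class I, 13 cytokine, 12 macrophage and 12 pan-haematopoietic genes were called. The members named moved the same way in 4 of 4 pairs.

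Markers of the DC subsets moved in both directions with Ikzf2. Of 11 tested pDC genes 2 rose and 3 fell. Risers were Tcf4, the master regulator of pDCs (0.90 ± 0.25; 214.7 against 97.7 CPM, adjusted p = 0.0235), and Runx2 (0.80 ± 0.18). The fallers included Bst2, a surface marker used to sort pDCs and an interferon-induced gene (-1.60 ± 0.20; 890.0 against 2279 CPM). The pDC list did not pass (adjusted p = 0.188), and its median of 0.51 had the opposite sign to its mean of -0.43. Of 11 cDC1 genes 2 rose, including Cadm1 (2.96 ± 0.57), and 5 fell, including Tlr3 (-3.85 ± 0.34), with the list at adjusted p = 0.0807. The cDC2 list fell with 3 of 9 genes called (adjusted p = 0.021, and adjusted p = 0.29 with an estimated correlation). Falls were also called for mature DC genes (5 of 10, adjusted p = 0.0042), pattern recognition genes (8 of 12, adjusted p = 0.00517) and stress genes (7 of 12, with 2 higher, adjusted p = 0.0229). They were called too for cell cycle genes (8 of 18, adjusted p = 0.0428), endothelial, epithelial and muscle genes (4 of 6, adjusted p = 0.00483), T and NK cell genes (2 of 3, adjusted p = 0.00497) and the erythroid and platelet list (1 higher and 1 lower of 3, adjusted p = 0.00102). None of these calls held with an estimated correlation (adjusted p of 0.206 to 0.479). Fibroblast genes (2 higher and 7 lower of 20, adjusted p = 0.0689) and contractile genes (2 higher and 4 lower of 11, adjusted p = 0.146) did not pass as lists. Nor did neutrophil and mast cell genes (1 higher and 1 lower of 3, adjusted p = 0.327) and B cell genes (1 higher and 1 lower of 4, adjusted p = 0.287; median -0.24 with the test pointing up). The delivered factors gave 2 higher and 1 lower of 6 (adjusted p = 0.0262, and adjusted p = 0.321 with an estimated correlation). Besides Ikzf2, Prdm1 was higher in SII (2.995 ± 0.439; 14.77 against 1.26 CPM, adjusted p = 0.00224; 4 of 4 pairs). Spi1 was lower (-4.52 ± 1.07; 0.0993 against 1.82 CPM, adjusted p = 0.0135; 3 of 4 pairs). Adjusted over the list alone, 7 pDC, 7 cDC1, 3 cDC2, 5 mature DC, 9 pattern recognition, 9 stress, 8 cell cycle, 11 fibroblast and 7 contractile genes were called. Leaving out the SI8 library of the Clec9a line at day 3 lowered the count to 3575, the SII library of that line at day 3 to 3712 and the SII library of the hCD2 line at day 3 to 3845. Cells with at least 10000 UMIs gave 1611 genes. Without both shallow SI8 libraries of the hCD2 line 1618 genes were called, and Dlk1, Saa3 and Lyz2 missed the threshold.

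**Figure D2:**
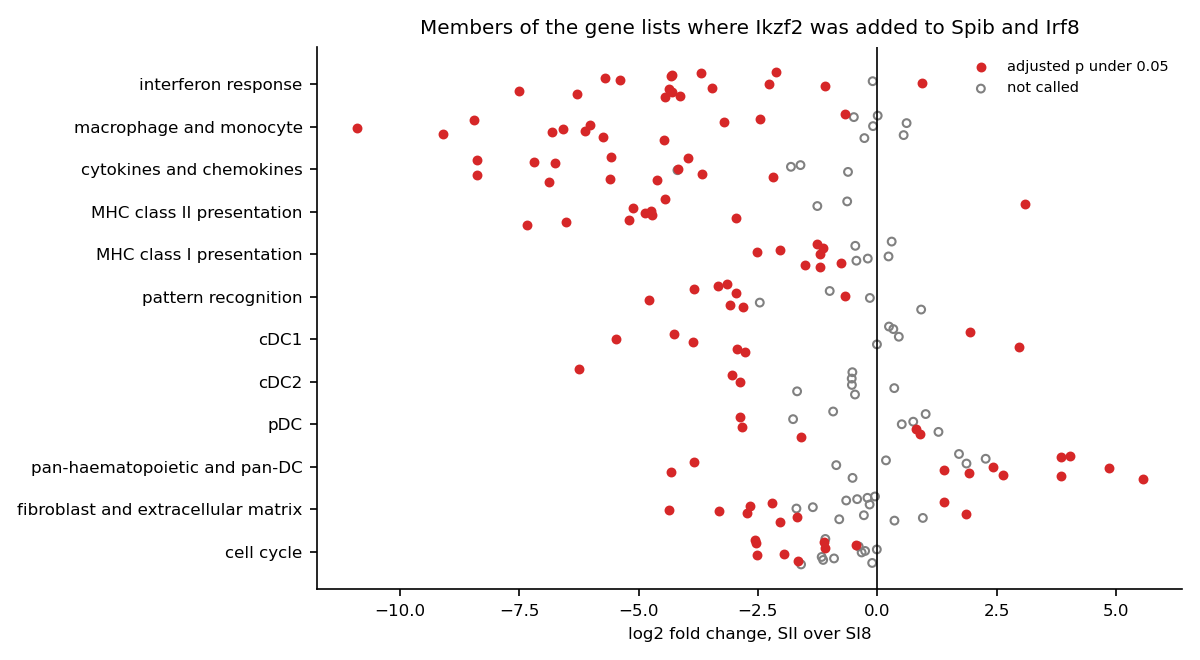
Log2 fold change of SII over SI8 for each tested member of 12 gene lists (x axis; filled points are genes with an adjusted p under 0.05 by edgeR over 4 pairs of libraries). Interferon response genes fell in 15 of 17 cases and pan-haematopoietic genes rose in 9 of 17.

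Prdm1, the factor that separates PIP from PI4, was set against 1 library of each set per day. The PI4 side was of lower depth, with 67.8% and 60.3% of barcodes under 10000 UMIs at day 3 and day 9 and a median mitochondrial share of 0.351% and 0.227%, against 1.36% and 1.77% of barcodes and a share of 3.33% and 2.74% in PIP, so RNA quality moved with this contrast. With all libraries in the fit 22 genes were called, 2 higher and 20 lower. Heatr5a rose by 2.29 ± 0.32 (68.9 against 15.7 CPM, adjusted p = 0.0433). The lipid droplet enzyme Hsd17b11 (-5.11 ± 0.44, adjusted p = 0.00356) and the nudix hydrolase Nudt19 (-4.10 ± 0.33) fell, as did Tmbim1 (-3.23 ± 0.41, adjusted p = 0.0247) and the ubiquitin ligase Nedd4 (-1.74 ± 0.26, adjusted p = 0.0475), in 2 of 2 pairs. Olfml2a, with 2 counts in PIP, had a ratio of 4255 in favour of PI4 (1178 to 35140, adjusted p = 0.0117), and the myeloid inhibitory receptor Cd300a a ratio of 106.8 (29.6 to 882.2). Prdm1 itself stood at 75.8 against 1.87 CPM (5.55 ± 1.17), with an adjusted p of 0.125. The count was 0 without PIP at day 3, 6 without PIP at day 9, 4 and 3 without PI4 at day 3 and day 9, and 9 to 13 without other single libraries. It was 646 without PI8 at day 3, and 660 (235 higher, 425 lower, the 22 among them) without the library labelled PI8 day 9, where the share that was higher went from 9.1% to 35.6%. DESeq2 called 628 genes, 27.4% of them higher, and the 4 libraries of these sets alone gave 1305.

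Without the library labelled PI8 day 9, Prdm1 passed the test (adjusted p = 0.00248). Higher in PIP were the gelatinase Mmp9 (5.44 ± 0.73; 63.7 against 1.71 CPM, adjusted p = 0.00686) and the cDC2 lectin Cd209a (3.54 ± 0.64; 253.2 against 23.8 CPM, adjusted p = 0.0187). So were Ctsk (2.94 ± 0.60; 3344 against 522.9 CPM) and Mfge8, an opsonin of apoptotic cells (2.68 ± 0.45), in 2 of 2 pairs. Lower were Cxcl13 (at least 3133-fold), the growth factor Ptn (-6.18 ± 1.27), fibronectin Fn1 (-3.36 ± 0.36; 71.5 against 875.5 CPM, adjusted p = 0.00261) and the cytokines Il1a (-5.39 ± 0.68), Il6 (-4.92 ± 0.93) and Ccl2 (-3.03 ± 0.67; 480.5 against 4009 CPM). In the MHC class II list 3 of 12 genes fell (5 adjusted over the list alone), including H2-Ab1 (7.68 against 74.4 CPM; -3.15 ± 0.53, adjusted p = 0.0137) and the costimulatory ligand Cd80 (-4.66 ± 0.80). Fibroblast genes fell in 4 of 20 cases (6 adjusted over the list alone), and neither list passed the threshold (adjusted p = 0.074 for each).

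The libraries labelled PIB were compared with PI8 to ask what Batf3 added. Xcr1, the chemokine receptor that marks cDC1s, averaged 172.5 CPM in PIB and 0.868 CPM in PI8 (7.65 ± 1.02; higher in 2 of 2 pairs), with an adjusted p of 0.101. No gene was called by edgeR (0 of 16090; 2987 at an unadjusted p under 0.05), while DESeq2 called 1281, 361 higher and 920 lower. The pan-haematopoietic, pDC, erythroid and platelet, and delivered factor lists were lower in PIB (adjusted p = 0.0285 for each), as was the endothelial, epithelial and muscle list (adjusted p = 0.0193), each with adjusted p = 0.178 with an estimated correlation. Their members were not called, although 10 of 17 pan-haematopoietic genes passed adjusted over the list alone. The library labelled PI8 day 9 entered the PI8 mean of this contrast. Without it PI8 was 1 library and 40 genes were called, 3 higher and 37 lower. Xcr1 (6.96 ± 0.91, adjusted p = 0.0385) and the kinase Nrk (4.85 ± 0.76) were higher. Cd209a (-8.42 ± 0.95; 0.168 against 17.5 CPM, adjusted p = 0.0242), the macrophage elastase Mmp12 (-5.48 ± 0.81) and Cd52 (-5.14 ± 0.75) were lower. The integrin Itgax that encodes CD11c (-4.82 ± 0.72) and Ms4a6d (-3.35 ± 0.33) were also lower, at the 1 day with a pair. The cDC2 list fell (1 of 11 genes; 3 over the list alone, adjusted p = 0.0298, and adjusted p = 0.125 with an estimated correlation). The macrophage list fell as well (0 of 18; 5 over the list alone, adjusted p = 0.0298, and adjusted p = 0.0835 with an estimated correlation). Without PI8 at day 3, which leaves the library labelled PI8 day 9 alone on its side, 7364 genes were called.

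The remaining contrasts gave few genes. PI8 was compared with SI8 in the Clec9a line, Spi1 against Spib. It gave 0 calls by edgeR (2576 at an unadjusted p under 0.05; 883 by DESeq2), 7328 without PI8 at day 3, and 11, all higher in PI8, without the library labelled PI8 day 9. Among the 11 were Spi1 (6.36 ± 0.83, adjusted p = 0.0426), creatine kinase Ckb (4.61 ± 0.62; 933.5 against 30.8 CPM), the arginine:glycine amidinotransferase Gatm (4.73 ± 0.52, adjusted p = 0.028), Cldn1 (5.47 ± 0.74) and Ms4a6d (2.68 ± 0.33). Between Irf4 and Irf8 arms the single call of 14339 genes was Irf8 itself (-6.87 ± 0.46; 0.340 against 49.9 CPM, adjusted p = 0.0207; all 4 Irf4 libraries below all 4 Irf8 libraries). This call was lost without PI8 at day 3, PIB or PI4 at either day or PIP at day 9. Irf4 stood at 13.1 against 0.723 CPM (4.92 ± 1.71, adjusted p = 0.648). DESeq2 called 335 genes there, 60.3% of them higher, and an additive fit over 16 libraries called 69. The hCD2 line differed from the Clec9a line at 3 genes, all lower, of which Gt(ROSA)26Sor, the noncoding transcript of the Rosa26 locus that carries the tdTomato reporter, fell by 4.42 ± 0.29 (7.89 against 167.8 CPM, adjusted p = 0.00274; 4 of 4 pairs). It lost its call in the additive fit over 16 libraries (adjusted p = 0.469). The count rose to 25 without SII of the hCD2 line at day 9 and to 6 with a block of 4 pairs, and DESeq2 called 66, 63.6% of them higher. The B cell list was lower in the hCD2 line with no member called (2 of 4 adjusted over the list alone, adjusted p = 0.00443, and adjusted p = 0.309 with an estimated correlation). The day effect did not differ between Spi1 and Spib arms for any gene by edgeR (0; 514 at an unadjusted p under 0.05), and DESeq2 called 6.

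The distance from MEF to the splenic counterpart was described for each library without a test, since each population had 1 library. For genes higher in the splenic DC, the median share of the gap closed over the 16 transduced libraries was 7.58%, and for genes lower in the splenic DC it was 40.7%. The upward value depended on the settings and was 15.3% with a pseudocount of 1 CPM, 3.95% with 50 CPM and 3.29% over genes at least 16-fold apart. PI8 at day 3 closed 22.7% of the upward gap to cDC1 (95% interval from resampled cells 21.6 to 23.8), over 386 genes, and PIB closed 15.2% at day 3 and 14.7% at day 9. Towards cDC2 (543 genes) PI4 closed 12.8% and 8.03% and PIP 6.63% and 9.47%. Towards pDC (574 genes) SII of the Clec9a line closed 11% (10.2 to 11.4) and 7.14%, SII of the hCD2 line 5.66% and 6.19%, and SI8 closed 1.32% to 4.16% over 4 libraries. These shares were not specific to the counterpart. Towards cDC1, SII of the Clec9a line at day 3 closed 24.1% and PI4 at day 3 closed 21.4%, more than either closed towards its own counterpart. The library labelled PI8 day 9 stood apart with 34.0% of the upward gap and 94.1% of the downward gap. Across 4616 genes, which are not independent replicates, all 16 transduced libraries had a higher Spearman rho with cDC1 than with cDC2 or pDC. The rho with cDC1 of the library labelled PI8 day 9 was 0.706, against 0.436 and 0.439 with the MEF libraries. In every other transduced library the order was reversed, with 0.457 to 0.571 for cDC1 and 0.668 to 0.811 for MEF. The rho of the MEF libraries with the splenic libraries is not given here. Whether MEF had the same order among the splenic populations is left open.

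**Figure D3:**
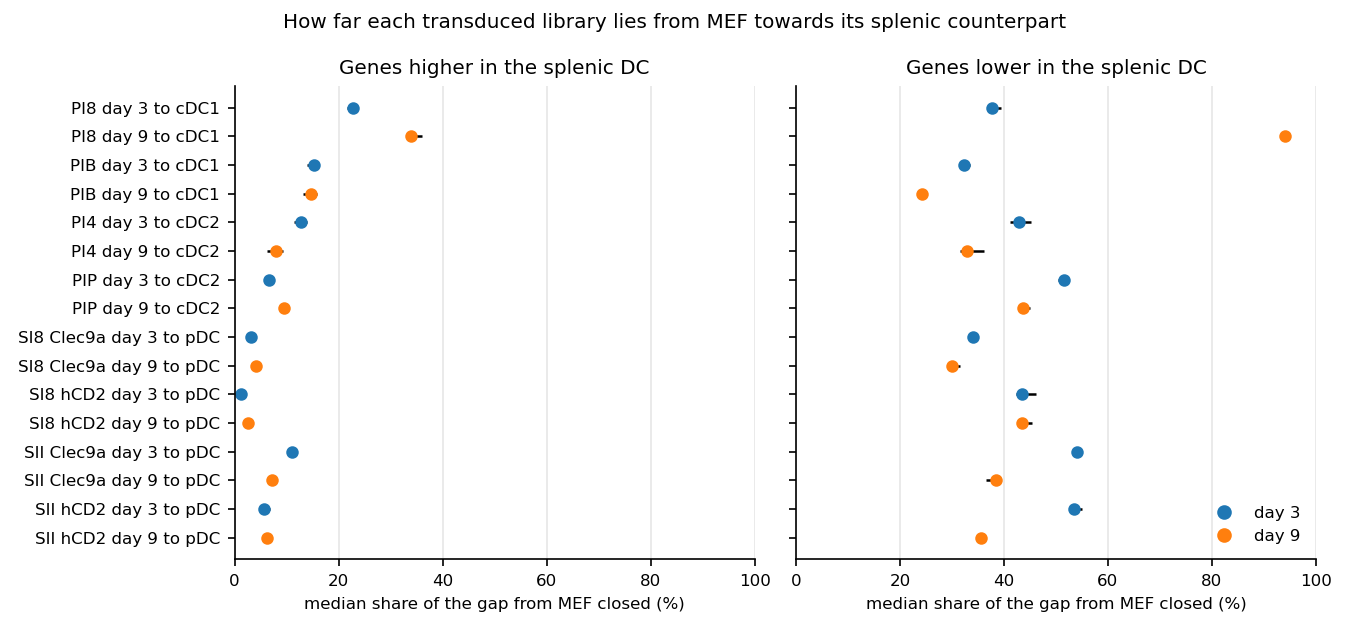
Median share of the distance from MEF to the splenic counterpart closed by each transduced library, in percent, for genes higher and genes lower in the splenic DC (points are libraries, blue day 3 and orange day 9; bars are 95% intervals from resampled cells). The upward shares, which depend on the pseudocount and the fold limit, lie between 1.32% and 34.0%, and the library labelled PI8 day 9 closed 94.1% of the downward gap.

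Day 9 libraries were set beside their splenic counterparts gene by gene. In PIB, Xcr1 reached 189.2 CPM (184.9 to 193.6) against 423.7 CPM in cDC1 and Ifi205 reached 182.6 against 311.0 CPM. Clec9a, a receptor for dead cells, had 0 UMIs (at most 0.0952 CPM) against 336.0 CPM and Wdfy4, needed for cross-presentation, had 1 UMI against 512.3 CPM. PIB was made in the Clec9a line alone. In the SI8 and SII libraries Clec9a averaged 0.0344 CPM in that line and 6.76 CPM in the hCD2 line. It was higher in the hCD2 line in 4 of 4 pairs but not called (adjusted p = 0.0717). The absence of Clec9a in PIB therefore cannot be told apart from the reporter line. Cd74 stood at 1339 CPM in PIB and 19150 CPM in cDC1. Genes far above cDC1 in PIB were Saa3 (4589 against 0.833 CPM), Ccl2 (3438 CPM), Ccl8 (2823 CPM) and Col1a2 (1920 CPM). In PIP, Cd209a reached 425.9 CPM (421.5 to 430.3) against 342.1 CPM in cDC2 and Clec12a 105.4 against 56.4 CPM, while H2-Ab1 reached 8.95 against 8734 CPM and Fcer1g 0.860 against 1223 CPM. Ccl8 stood at 86840 CPM in PIP and 0 in cDC2. In SII, Siglech, a pDC receptor, and Ly6d had 0 UMIs in both lines against 3050 and 3777 CPM in pDC, Tcf4 reached 262.7 and 238.0 against 2059 CPM, and Fn1 stood at 3952 and 4300 against 0.0941 CPM. In SI8, Saa3 reached 17340 and 15830 CPM and Lyz2 8531 and 9026 CPM, against 3.14 CPM of Lyz2 in pDC. The list of the counterpart subset lay below all 10000 random lists. It holds genes that mark the splenic population, so this rank was nearly fixed in advance and adds nothing to the medians. Its median log2 ratio was -3.50 for PIB and cDC1, -1.50 for PIP and -2.28 for PI4 and cDC2, and -5.53 for SII and pDC in each line. The MHC class II list gave medians from -2.07 (SI8, hCD2 line) to -5.20 (PIP), and the fibroblast list from 1.85 (PIP) to 4.61 (SI8, Clec9a line), apart from 0.12 in the library labelled PI8 day 9.

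Shares of cells with a UMI, after thinning to 5400 UMIs, gave the spread within libraries. Xcr1 was seen in 41.9% of PIB cells at day 3 (38.3 to 45.7; n = 706 cells) and 35.2% at day 9. It was seen in 0.985% of PI8 cells at day 3 and 84.9% of cDC1 cells. In MEF, which should lack it, the shares were 0 and 0.0579% at median depths of 18100 and 25927.5 UMIs, against 67270 and 64579 UMIs in PIB. The unthinned shares were 82.0% and 65.9% in PIB and 97.3% in cDC1. Cd209a was seen in 17.7% of PIP cells at day 3 and 47.7% at day 9 (44.8 to 50.6; n = 1184; unthinned 48.0% and 87.1%), in 47.5% of cDC2 cells (unthinned 58.5%), in 2.39% and 5.60% of PI4 cells and in 0 MEF cells. Ptprc was seen in 63.4% of SII cells of the Clec9a line at day 3 (61.3 to 65.5; n = 2074; unthinned 90.6%) and 17.1% at day 9 (unthinned 33.8%). It was seen in at most 2.10% of SI8 cells, in 0 MEF cells and in 96.4% of pDC cells. Siglech was seen in 100% of pDC cells and in 0 SII cells with or without thinning, with upper limits of 0.178% to 0.604% for cells with a captured UMI at this depth. Cd74 was seen in 7.78% and 9.03% of MEF cells (unthinned 19.3% and 25.1%), 82.8% of PI8 cells at day 3 and 13.9% of cells of the library labelled PI8 day 9. The SI8 libraries of the hCD2 line kept only 31 and 67 cells at this depth. PI4 at day 3 had a median of 4022.5 UMIs per cell, so most of its barcodes were left out. Its shares describe the deeper barcodes and are not those of the whole library. The sort on the reporter and, for splenic cells, on surface proteins can set such shares.

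**Figure D4:**
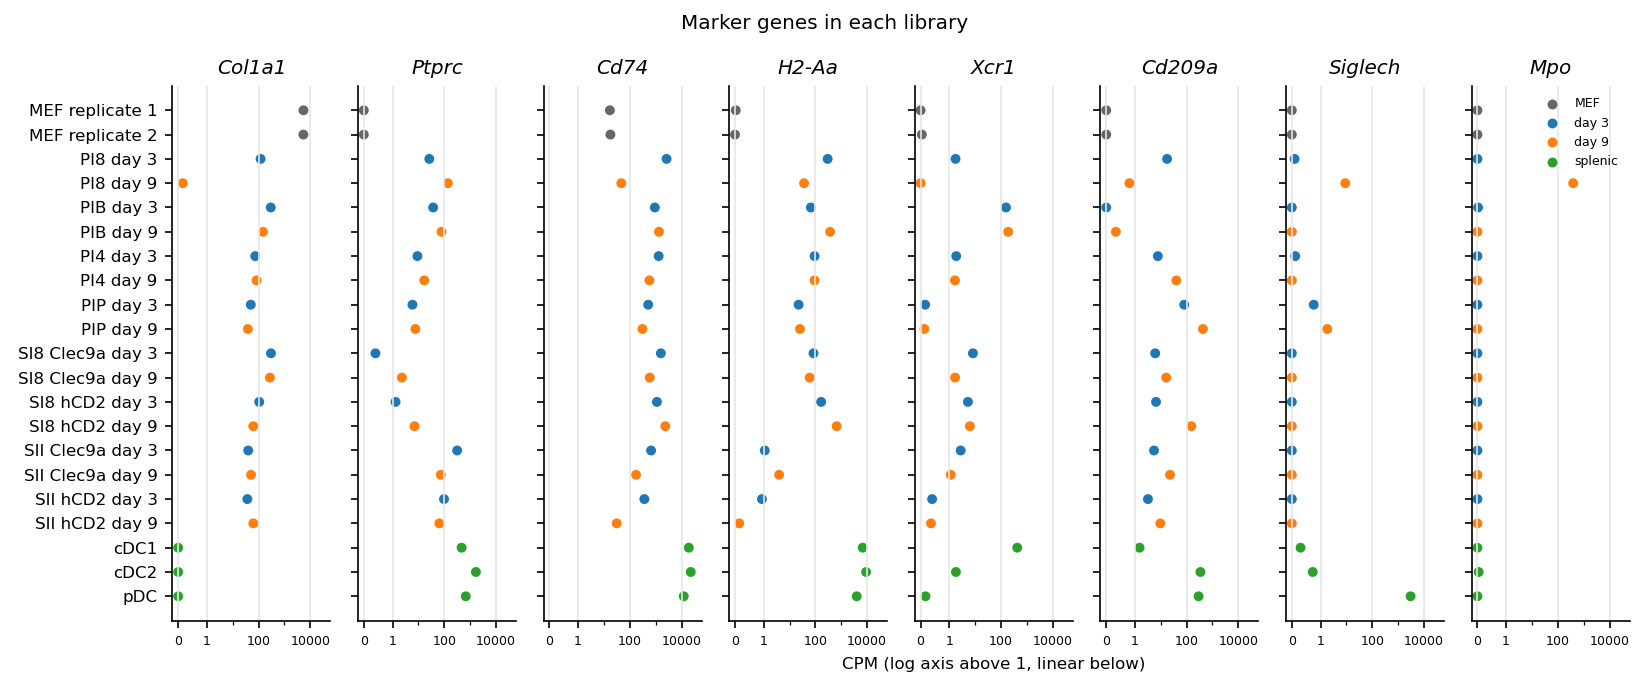
CPM of 8 marker genes in the 21 libraries (x axis logarithmic above 1 and linear below; grey MEF, blue day 3, orange day 9, green splenic). Xcr1 reached 189.2 CPM in PIB at day 9, Cd209a 425.9 CPM in PIP at day 9, and Siglech had 0 UMIs in the SII libraries at day 9.

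Clustering divided the 25991 cells into 15 clusters, 7 of which drew over 90% of their cells from 1 library. No cell of a transduced library fell into the MEF cluster, and 1 cell, of the library labelled PI8 day 9, fell into a splenic cluster. Clusters followed factor set in part, and SI8 cells were divided by reporter line and, in the Clec9a line, by day, and SII cells by day. Depth went with the division of SI8. Median UMIs were 2780 in the cluster of the hCD2 line, and 65817 and 10525.5 in the main clusters of the Clec9a line at day 3 and day 9. A cluster of 204 SII cells of the Clec9a line at day 9 had a median of 8430.5 UMIs. Line and day therefore cannot be told apart from depth for these clusters. SII cells at day 3 of both reporter lines made up most of a cluster of 3387 cells, PIP cells of both days most of a cluster of 2605 cells and PIB cells of both days most of a cluster of 1338 cells. Of the PI8 cells at day 3, 68.1% fell into the cluster of SI8 cells of the Clec9a line at day 3 and 23.6% into the PIP cluster. Clusters are given by number and size, without cell type names.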

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

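All 3 tests of the library labelled PI8 day 9 reported here were chosen after its values were seen. List sums and other summary quantities were compared among the 8 libraries of a day in 44 comparisons, and chance alone places a library far from the rest in about 1 of 20. In 8 of the 44 a library lay further from its nearest neighbour than chance allows at that rate, and 7 of the 8 were in the library labelled PI8 day 9. On a log2 scale, with 10 CPM added to each summed CPM, that library was lowest at day 9 for the fibroblast list (5.39; nearest other library 10.86), the contractile list (7.57; 10.38), the macrophage list (9.65; 12.38), the mature DC list (6.50; 8.73) and the cDC1 list (7.66; 9.02). It was highest for the cell cycle list (10.29; nearest other 7.28) and the B cell list (7.16; 5.41). The remaining result was the T and NK cell list, highest at day 3 in PIB (4.90; nearest other 4.07), where its sum was 19.9 CPM before that addition.

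The library labelled PI8 day 9 held few of the fibroblast transcripts seen in the other 15 transduced libraries. Col3a1 was seen in 0 of 649 cells thinned to 5400 UMIs, Cd74 stood at 47.0 CPM, and the most elevated genes relative to cDC1 were Ctla2a (1230 CPM), Ifitm1 (777.5 CPM), Prtn3, a protease of granulocyte precursors (564.7 CPM), and Car2 (537.1 CPM). A list of 12 bone marrow progenitor genes, written after these values were seen, summed to 2175 CPM there, to at most 25.2 CPM in other transduced libraries and to 325.7 CPM in the highest splenic library. Of its genes 2 were also in the other lists, 3 reached 10 CPM in a splenic library and 1 in another transduced library. Besides Prtn3, its member Mpo reached 393.1 CPM.

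For this pattern low depth was tested first. With all libraries thinned to 2291128 UMIs, its median Spearman rho with the other transduced libraries was 0.586, and the lowest median of the others was 0.818, which depth would not produce. Cells further along towards cDC1 than the same arm at day 3 would need a cDC1 list at or above its day 3 sum of 733.5 CPM (724.0 to 743.1), and it was 191.5 CPM (180.7 to 202.7). Against this, the library closed 34.0% of the upward gap to cDC1 where PI8 at day 3 closed 22.7%, though also 33.7% to cDC2 and 30.2% to pDC, and its rho with cDC1 was 0.706 against 0.529. These measures point different ways, so this explanation stays open. Cells other than the transduced fibroblasts of the other libraries, such as haematopoietic progenitors, may be the source, since the fibroblast list stood at 1.73% of the lowest other transduced library. The stated sort on tdTomato would remove cells without the reporter, and Spi1 (215.4 CPM) and Irf8 (84.3 CPM), both also expressed by progenitors, do not separate an exchanged sample from other cells in the culture or a biological effect of the factors, which stays untested with 1 library.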

How the results depend on the processing

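Alternatives that left out the library labelled PI8 day 9 or both SI8 libraries of the hCD2 line, or that kept only cells with at least 10000 UMIs, were chosen after the data were seen. The genes named for the highest and lowest fold changes of the main fits, 59 calls over all contrasts, were followed through the alternatives. None of them turned its direction under any alternative run. Other genes named in the text were not counted here. DESeq2 turned the balance of the calls, with 61.2% of genes higher against 47.5% in the main test for day 9 against MEF, and 60.3% for Irf4 against Irf8 arms and 63.6% between reporter lines, where the main test called only lower genes. Without MEF replicate 1 or 2 the share that was higher at day 3 against MEF went from 50.9% to 26.5% and 27.8%. RLE scaling, the stricter filter on cells and removal of doublets left every count of genes within 1.5 times its main value, as did dropping the low-count filter except for the reporter lines (10 genes against 3). Among the genes followed, 59 of 59 kept their call under RLE scaling and under the stricter filter, and 54 of 54 with an adjusted p under DESeq2 (the other 5 were given none). Calls were kept for 51 of 59 in thinned counts, 50 of 59 with cells of at least 10000 UMIs and 42 of 42 without the library labelled PI8 day 9. When single libraries were left out, 752 of 872 calls were kept.

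DESeq2 called 3289 genes for day 9 against MEF, 4371 for day 3 against MEF, 1203 between days, 335 for Irf4 against Irf8 arms, 66 between reporter lines, 1281 for Batf3, 628 for Prdm1, 883 for Spi1 against Spib and 6 for the interaction of day with Spi1 or Spib. In counts thinned to the shallowest library there were 1098 and 1700 genes against MEF at day 9 and day 3, 7 between days, 0 for Irf4 against Irf8 arms, 3787 for Ikzf2, 1 for Batf3, 8 for Prdm1 and 3 for Spi1 against Spib, and fewer counts per gene account for part of that by construction. Day 9 and MEF libraries alone gave 1058 genes, and the 4 PIP and PI4 libraries alone 1305. The additive fit over 16 libraries gave 69 genes for Irf4 against Irf8 arms, 3821 for Ikzf2 and 0 for the reporter lines.

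Without the library labelled PI8 day 9 the counts were 3310 and 4451 against MEF at day 9 and day 3, 1272 between days, 40 for Batf3, 660 for Prdm1 and 11 for Spi1 against Spib. With that library left out and cells of at least 10000 UMIs they were 3199, 4519, 875, 11, 478 and 4. Cells of at least 10000 UMIs alone gave 3 genes between days, 1611 for Ikzf2 and 2 for Batf3. Without both SI8 libraries of the hCD2 line there were 3 genes between days, 1618 for Ikzf2 and 12 for Prdm1. The cause of these shifts was not tested beyond the values given.

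The labels pair days within an arm and SI8 with SII within a line and day. Without the arm as a block, 0 genes were called between days. With a replicate block of 4 pairs the reporter lines gave 6 genes and Ikzf2 4739 against 5798. The block was fitted for these 2 contrasts alone. It changed the call of none of the 17 genes named for their highest and lowest fold changes. Other genes named for these contrasts were not followed. Leaving out 1 library at a time, the counts ran from 264 to 3310 and from 561 to 4451 against MEF at day 9 and day 3, from 3 to 1272 between days, from 0 to 7364 for Batf3, from 0 to 660 for Prdm1, from 0 to 7328 for Spi1 against Spib, from 0 to 1 for Irf4 against Irf8 arms, from 3575 to 5306 for Ikzf2 and from 2 to 25 for the reporter lines, and stayed at 0 for the interaction. A library left alone on its side is assumed to vary like the others.

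Of all list tests 33 passed with fry and 1 with camera. The median upward gap closed, 7.58%, became 15.3% with a pseudocount of 1 CPM, 3.95% with 50 CPM, 3.29% over genes at least 16-fold apart and 9.23% with cells of at least 10000 UMIs, and ran from 7.45% to 7.58% without either MEF library. The downward gap, 40.7%, became 28.8%, 52.7%, 49.3% and 38.4% in the same order and ran from 40.5% to 40.9%. Cd74 was seen in 53.4% of all transduced cells after thinning, 81.2% without thinning and 46.7% at 2700 UMIs. Clusters numbered 15 at resolution 0.5, 11 at 0.25 and 20 at 1.0. The SI8 libraries of the hCD2 line, with 98.3% and 97.4% of cells under 10000 UMIs, limit what can be seen in single cells.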

Other observations

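S100a8, which encodes a calcium-binding subunit of calprotectin in neutrophils and inflammatory macrophages, was most abundant in SI8 libraries at day 9, without its usual partner. It stood at 376.7 and 258.0 CPM at day 3 and at 2438 and 1727 CPM at day 9 in the Clec9a and hCD2 lines, against 2.09 and 2.67 CPM in MEF, while S100a9, the other subunit, had 0 UMIs in all 4 SI8 libraries. S100a8 was not limited to SI8, with 269.8 CPM in PI4 and 160.4 CPM in PIP at day 9. It made up nearly the whole sum of the neutrophil and mast cell list in SI8. With Ikzf2 added, S100a8 fell by 8.37 ± 1.37 on the log2 scale in 4 of 4 pairs. The macrophage list summed to 18310 and 15370 CPM in SI8 at day 9 against 10820 and 10930 CPM in MEF. Lyz2 alone gave 8531 and 9026 CPM of the 2 SI8 sums, and Spp1, of the same list, averaged 7406 CPM in MEF. Each side thus rests in large part on a single gene, and the sums do not rank the list as a whole. These sums were not tested against each other.

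The list sums in this paragraph are of single libraries and were not tested. In 7 of 8 day 9 libraries the MHC class I sum was above both MEF libraries and the interferon response sum below both. For PI4 at day 9 the interferon response sum, 6419 CPM, was level with the lower MEF library. At day 3 this sum lay above both MEF libraries in PIP (7929 CPM), PI4 (7820 CPM) and SI8 of the Clec9a line (6688 CPM), and below both in the other transduced libraries. Between factor sets at day 3 the 2 lists ran in nearly the same order, and both were lowest in SII of the hCD2 line (3529 and 760.8 CPM). The MHC class I list summed to 13950 CPM in PIP at day 9 and 11770 CPM in PI4 at day 9, against 4772 and 4816 CPM in MEF and 11840 CPM in pDC. Over both days of PI4 and PIP, B2m averaged 4922 CPM and H2-D1 2071 CPM, and Isg15 of the interferon response list averaged 3226 CPM. A few genes thus carry much of these sums, which do not rank the lists as a whole. No member of the MHC class I list was called at day 9 against MEF. The interferon response list summed to 4777 CPM in PIP at day 9 and to 760.8 to 1363 CPM in SII, where both MEF libraries had 6483 and 6421 CPM. In SI8 at day 9 the MHC class I list summed to 10530 and 8473 CPM and the interferon response list to 3382 and 1963 CPM, and in PIB at day 9 they summed to 5510 and 3145 CPM. Cell cycle genes summed to 82.3 to 293.7 CPM in transduced libraries other than the library labelled PI8 day 9, which had 1244 CPM, and to 112.4 and 113.0 CPM in MEF.

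Of the tests that follow, those of Malat1 and of mitochondrial counts in the PI4 libraries and the splits within arms or pairs were chosen after the result was seen. In PI4, 483 of 712 barcodes at day 3 and 252 of 418 at day 9 held under 10000 UMIs, and these had a median of 0.236% and 0.185% mitochondrial counts against 2.24% and 0.955% in the other barcodes. Nuclei without cytoplasm would raise the nuclear transcript Malat1, which instead stood at 21.1% and 34.4% of its level in the other barcodes. Whole cells that lost depth alike for all genes would keep the mitochondrial share, and the tests gave a ratio of 5.15 between the shares at day 9, so the tables argue against both. Cytoplasmic RNA without nuclei could account for low Malat1, but other nuclear noncoding transcripts stood at 56.6% at day 3 and 105% at day 9, so this explanation stays open. No biological explanation was tested.

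The response to Ikzf2 may depend on the shallow SI8 libraries of the hCD2 line, in which few cells reach 10000 UMIs. When genes were called on 3 pairs and read in the pair left out, 97.3% of 2152 genes kept their direction in the day 3 pair of the Clec9a line, 89.7% of 4134 in its day 9 pair, 94.4% of 2443 in the day 3 pair and 87.2% of 4195 in the day 9 pair of the hCD2 line. The calls read in the day 3 pair of the Clec9a line drew on the day 9 pair of that line as well. Genes moved by the hCD2 line alone could thus drop out before they were read. In the day 3 pair 0.93% (SI8) and 0.48% (SII) of barcodes held under 10000 UMIs. For those 2152 genes alone, this argues against low-UMI barcodes of the hCD2 line as the whole cause. The SI8 library of the Clec9a line at day 9 had 46.8% such barcodes, so its pair cannot decide this. Other biological or technical differences between these sets of cultures stay open.

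Other splits of the same libraries were used to ask whether chance could give as many genes. For Ikzf2 1 of the 8 splits that keep the 4 pairs gave 5798 genes, the real one, and the highest other gave 0, and 8 splits are too few for a share under 0.05. The highest other was also 0 in 33 splits that ignore the pairs. For Irf4 against Irf8 arms 1 of 34 splits, the real one, gave 1 gene, and the highest other gave 0. That gene is Irf8, a delivered factor that defines the arms, so these splits say nothing about a response. For day 9 against day 3 the splits exchanged the days within arms, since splits that ignore the arms divide fewer pairs. With all libraries 2 of 40 drawn splits gave at least the real 13 genes, and the highest other gave 46, so chance cannot be excluded. That split exchanges the days of PI8 alone, which points to the PI8 libraries as a structure of the samples. Without the library labelled PI8 day 9 the real split gave 1272 genes, 1 of 40 drawn splits did so, and the highest other gave 1. The real split thus stood alone among the drawn splits that keep the pairs, of 64 possible. Both these splits and the omission of that library were chosen after the data were seen, so chance is not excluded. In 30 drawn splits that ignore the arms, the real split alone reached its count in both cases, and the highest others were 2 genes with all libraries and 958 without that library. The split with 958 genes divides only the SII arms, and by day. For the reporter lines 1 of 8 splits that keep the pairs gave 3 genes, the real one, and the highest other gave 0, again too few for such a share. Among 33 splits that ignore the pairs the highest other gave 49, and that split, which follows factor set by day, points to a structure of the samples. For the interaction of day with Spi1 or Spib all 35 splits gave 0 genes, as many as the real one. These shares were not adjusted for the number of contrasts asked about.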
